A study of Mus musculus with 4 samples.

How the data were processed

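Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against Nrf2 was carried out on mouse esophagus of 3 genotypes, C57BL/6 by strain per the labels. These were wild-type, a knockout of Nrf2 (Nrf2KO) and a knockout of Keap1 (Keap1KO), each with 1 ChIP library, and a pooled input DNA library was the remaining sample. Nrf2 (gene symbol Nfe2l2) is a transcription factor of the oxidative stress response, and Keap1 is the adaptor protein that targets it for degradation. Tissue was frozen, libraries followed the usual Illumina procedure and the ChIP was done by a commercial laboratory, per the labels' protocols.

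BWA (a read aligner), MACS2 2.1.0 (a peak caller) and the genome build mm10 are named in the submitters' processing notes. Their parameters, the read length, the sequencing depth and any scaling between libraries are not given in the sources used here. The deposited table holds 1 row for each of 1940 genes with called intervals in or near them. Per the file headers, the values used here are the signal of each ChIP library, an average peak height per gene, and a flag for a called interval. No unit of the deposited signal is stated. In the 1681 genes with 1 active region (called intervals merged between libraries), 100% of the 5043 heights were exactly whole numbers, and the other heights were rebuilt as means over the active regions of a gene. Depth per library is unknown, so no counting interval is given for a height, and a difference in library size between genotypes cannot be excluded. The input library has no column in the table and was not analysed here.

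Intervals lay in a gene, up to 10586 bp upstream of its start or up to 10233 bp beyond its end. Interval numbers ran to 2729 for Keap1KO and to 277 for wild-type. Of the numbers up to those, 1059 and 222 were not in the table, and the reason is not given. The counts here are of the intervals listed near genes. The absent part was larger in wild-type, so the balance of calls between libraries may differ over all intervals. Positions were computed from each gene's start, strand and the listed distance, and every interval came out at a single position from all of its genes. Of the 1940 genes, 1878 were matched by identifier to a RefSeq table of GRCm38.p6, and 78.3% of these had both ends within 1 kb of its coordinates. The table places an interval upstream of, in or downstream of a gene, without exons or introns.

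Neighbouring genes share intervals, so gene rows are not separate measurements. The 1727 intervals were merged to the number of active regions stated for each gene, which gave 1684 active regions, and the largest distance merged was 704 bp. Heights were then solved by least squares from the gene means, with a largest residual of 0.00186. Regions listed under exactly the same genes are given only as 1 mean, and were kept together as 1 locus. This gave 1460 loci, of which 1279 held 1 region and 181 held more, up to 5. Heights in the text are per locus, and a rule on the height of a region used the height of its locus.

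With 1 library per genotype no test between genotypes was possible. Comparisons use log2 ratios of heights with a pseudocount of 1, which understates the change of low loci, and folds are on the same scale. A rule of 2-fold describes size only. Intervals of medians are 95% order-statistic intervals, intervals of shares are exact (Clopper-Pearson) 95% binomial intervals, and intervals of differences in the closing section are 95% bootstrap intervals. They cover the spread over loci or genes in these libraries, which are not replicates, and not the variation between animals. Every locus was called in wild-type or in Keap1KO. Heights in those libraries were thus selected upwards where they were called and downwards where they were not. No listed locus was called in Nrf2KO. Whether loci called in Nrf2KO were left out of the table is not known, so selection of its heights downwards cannot be excluded.

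The groups, comparisons, 17 gene lists and the rule for named loci were fixed before the data were examined. The design had foreseen a height for every region, whereas the table gave means per gene, and the loci stand in for regions. A gene was represented by its locus of highest mean height over the 3 libraries. The median log2 ratio of each list with at least 3 loci was placed among 10000 random lists of as many loci matched on mean height in 10 bins. The share of each list with a locus was set beside that of the 21900 protein-coding genes of the RefSeq table. The rule for named loci took the 10 largest Keap1KO over wild-type ratios and the 10 largest Keap1KO over Nrf2KO ratios among loci called in Keap1KO with a height of at least 18, the median there. It took the 5 lowest Keap1KO over wild-type ratios and the 5 largest wild-type over Nrf2KO ratios among loci called in wild-type with a height of at least 13, the median there. It added the 5 highest loci in Nrf2KO, the 20 genes of the 8 Nrf2 pathway lists with the highest Keap1KO height, and up to 2 genes of each other list by mean height. Genes named outside this rule are said to be so.

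Alternatives tried were pseudocounts of 0.5 and 5, a stricter call and a call by height alone, a filter on mean height, rules of 1.5-fold and 3-fold, averaging all regions of a gene, a limit of 10 kb to the gene start and a distance of 5 kb in place of 1 kb. Chosen after seeing the data were 1 value per gene, loci more than 1 kb from a gene start, loci not called in wild-type, a minimum of 5 loci per list and a scaling of wild-type to Nrf2KO. That scaling used the loci with a Keap1KO height up to the median. It was first made on their median height, which was 4 in both libraries and so moved nothing, and was then changed to their mean height (factor 0.957). A planned search for the antioxidant response element, the DNA motif of Nrf2, was not run because no genome sequence was used here.

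The solver and the statistics were tested on simulated data. Rebuilt region heights had a largest error of 0. With Poisson noise around the wild-type heights of the 1460 loci plus 5, the 2-fold rule was passed by 98.0% of 100 loci raised 4-fold, 100% of 100 raised 8-fold and 5.87% of 1260 unchanged loci. The real heights were lower, with a median of 5 in wild-type and 4.33 in Nrf2KO. The share of unchanged loci that noise alone would pass was not measured at those heights. Of 100 random lists of 8 loci, 7.00% lay above the 95th percentile. Those lists were drawn from all loci alike, so lists made mostly of tall loci were not checked. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.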

Results

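Binding of Nrf2 was profiled by ChIP-seq in the esophagus of wild-type, Nrf2KO and Keap1KO mice, with 1 library per genotype and no replicates. The Nrf2KO library gives the background of the same antibody without its target, and the Keap1KO library the signal without the protein that targets Nrf2 for degradation. Over 1460 loci on 20 chromosomes, the median peak height was 5 in wild-type (quartiles 3 and 7, maximum 32), 4.33 in Nrf2KO (3 and 7, maximum 17) and 18 in Keap1KO (14 and 23.4, maximum 194). Depth per library is unknown, and every comparison below is of single libraries.

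The targeted genes were looked at first. The locus of Nfe2l2, which encodes Nrf2, lay 561 bp into the gene on chromosome 2 (position 75703936, GeneID 18024), with heights of 17 in wild-type, 7 in Nrf2KO and 78 in Keap1KO. Keap1 (chromosome 9, GeneID 50868), named as a targeted gene and outside the rule for named loci, had 3 regions, all less than 1 kb into the gene, with mean heights of 6.33, 7.67 and 19.3. These are heights of antibody signal near gene starts and do not check either deletion.

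Calls were concentrated in the Keap1KO library. Of the intervals near genes, 1671 were called in Keap1KO, 56 in wild-type and 0 in Nrf2KO. Intervals absent from the table, a larger part in wild-type than in Keap1KO, are not in these counts. Of the wild-type regions, 43 were also called in Keap1KO (76.8%, 63.6 to 87.0), among them those at Txn1, Prdx1, Nfe2l2 and Gstm1, and 13 were called in wild-type only. By gene, 1923 were listed with a Keap1KO interval, 81 with a wild-type interval and 64 with both. With a stricter call 903 Keap1KO and 11 wild-type regions were left. With every region of at least 12 in height counted as called, there were 1592 in Keap1KO, 49 in Nrf2KO and 82 in wild-type, and 71 were shared by wild-type and Keap1KO.

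Heights in Keap1KO exceeded those in wild-type at 1442 of the 1460 loci. Thioredoxin (Txn1), a small protein that reduces disulfides, had the tallest locus of the table, 341 bp upstream of its start on chromosome 4 (position 57956752, GeneID 22166), with 25 in wild-type and 194 in Keap1KO, 7.50-fold higher. Srxn1, which encodes the sulfiredoxin that repairs peroxiredoxins, went from 13 to 158 (11.4-fold). Nqo1, a quinone reductase, went from 12 to 105 (8.15-fold) at a locus 427 bp upstream of its start on chromosome 8 (position 107403632, GeneID 18104), which is also listed under Nob1. Prdx1, a peroxiredoxin, went from 20 to 103 (4.95-fold).

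Over all 1460 loci the median log2 ratio of Keap1KO to wild-type was 1.74 (1.70 to 1.77). Keap1KO was at least 2-fold higher at 1285 loci and at least 2-fold lower at 4. At the 43 loci called in both libraries the median was 1.34 (1.19 to 1.78), and 32 of them were at least 2-fold higher in Keap1KO. Nearly all loci were chosen by a call in Keap1KO, which raises this ratio, and a difference in depth would move it too.

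**Figure D1:**
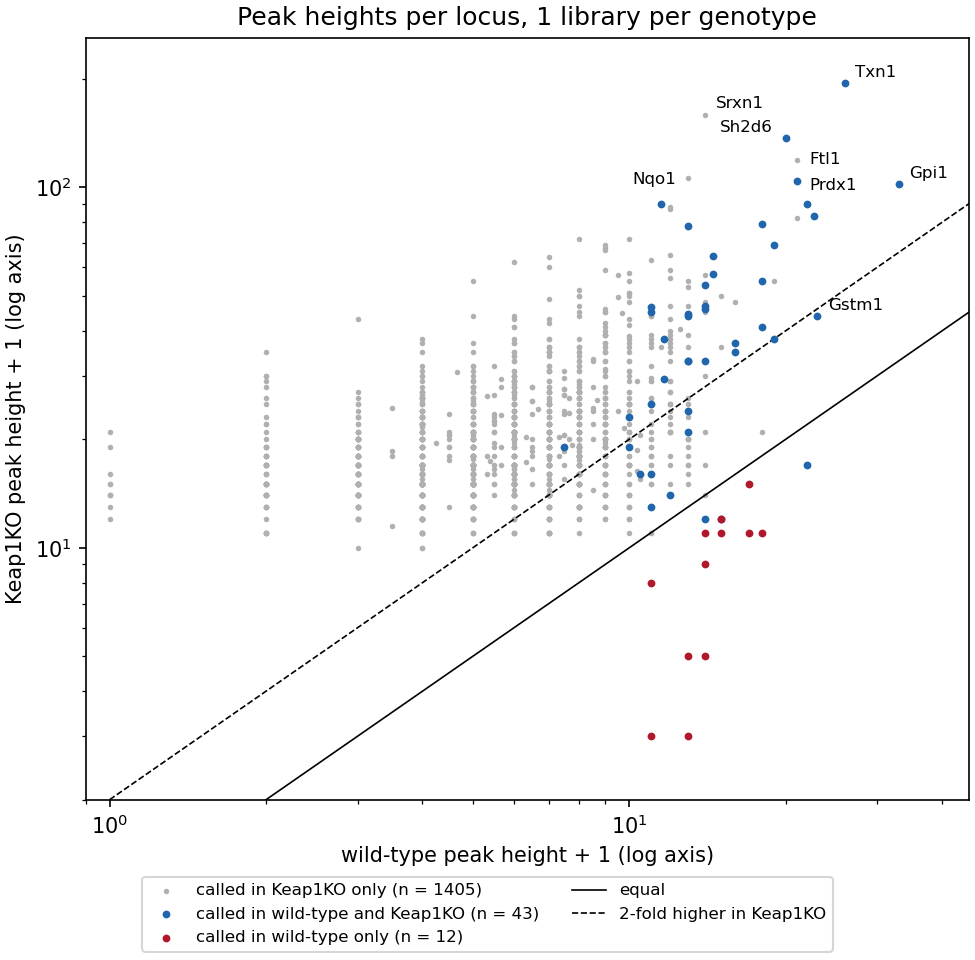
Peak height plus 1 in Keap1KO (vertical, log axis) against wild-type (horizontal, log axis) for 1460 loci, 1 library per genotype. Grey points were called in Keap1KO only (1405), blue points in both (43) and red points in wild-type only (12); the solid line marks equal heights and the dashed line 2-fold higher in Keap1KO, which 1285 loci reach.

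Among loci called in Keap1KO with a height of at least 18 there, the 10 with the largest Keap1KO over wild-type ratio were low in wild-type and did not form one of the fixed lists. At Fbxo21 and Ankhd1 wild-type was listed at 0, with 20 and 18 in Keap1KO. Wild-type was 1 or 2 at the others, which were Map1b (Keap1KO 34), Vipr2 (29), Akr1b8 (29), Sort1 (28), Ubap1 (42), Sh2d5 (27), Tspan17 (25) and Dync1h1 (24). At all 10 except Ubap1 and Tspan17, wild-type lay below Nrf2KO, and Keap1KO was fewer-fold above Nrf2KO than above wild-type. At Fbxo21 the folds were 5.25 and 21. Akr1b8, an aldo-keto reductase, was the only pathway list gene by which one of these loci was named. Among loci called in wild-type with a height of at least 13 there, the 5 with the lowest ratio were those of Pwp1 (13 in wild-type, 4 in Keap1KO), Ppm1a (17 and 10), Gabpa (13 and 8), Ufl1 (16 and 10) and Arl15 (14 and 10), these 5 within 1 kb of a gene start.

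Wild-type and Nrf2KO differed little over most loci and more at the glutathione transferase genes. The locus upstream of Gpi1, a glycolytic enzyme, was the tallest in wild-type, with 32 against 4 in Nrf2KO (6.60-fold, chromosome 7, position 34234016), and is also listed under Gm12758. Gstm1, a glutathione transferase, had 22 against 4 (4.60-fold), Tkt, a transketolase of the pentose phosphate pathway, 21 against 5 (3.67-fold), Fnbp1 13 against 2 (4.67-fold) and Rxra, a nuclear receptor, 13.5 against 3 (3.62-fold). Ftl1, the ferritin light chain, had 20 against 7 (2.62-fold), and Srxn1 13 against 10 (1.27-fold).

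Over all loci the median log2 ratio of wild-type to Nrf2KO was 0.19 (0.14 to 0.26). Wild-type was above Nrf2KO at 786 loci, equal at 152 and below at 522, and it was at least 2-fold higher at 274 and lower at 121. How many loci noise alone would place 2-fold apart at such low heights was not measured. At the 43 loci called in both wild-type and Keap1KO the median was 1.07 (0.71 to 1.32). At the 1405 loci not called in wild-type it was 0.17 (0.00 to 0.22); leaving out the called loci selects the wild-type height downwards. With a pseudocount of 5 the counts at least 2-fold apart were 58 higher and 14 lower.

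The excess of wild-type over Nrf2KO was larger at the loci with the highest Keap1KO heights. Loci were ranked by Keap1KO height into 10 groups of 146. In the highest group (34 to 194) the median log2 ratio was 0.58 (0.42 to 0.78), and wild-type was higher at 115 of 146 loci. In the lowest group it was 0.00 (−0.19 to 0.14), with wild-type higher at 61 of 146. Across the 1460 loci, which are not independent replicates, the ratio and the log2 Keap1KO height had a Pearson r of 0.183 and a Spearman rho of 0.164.

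**Figure D2:**
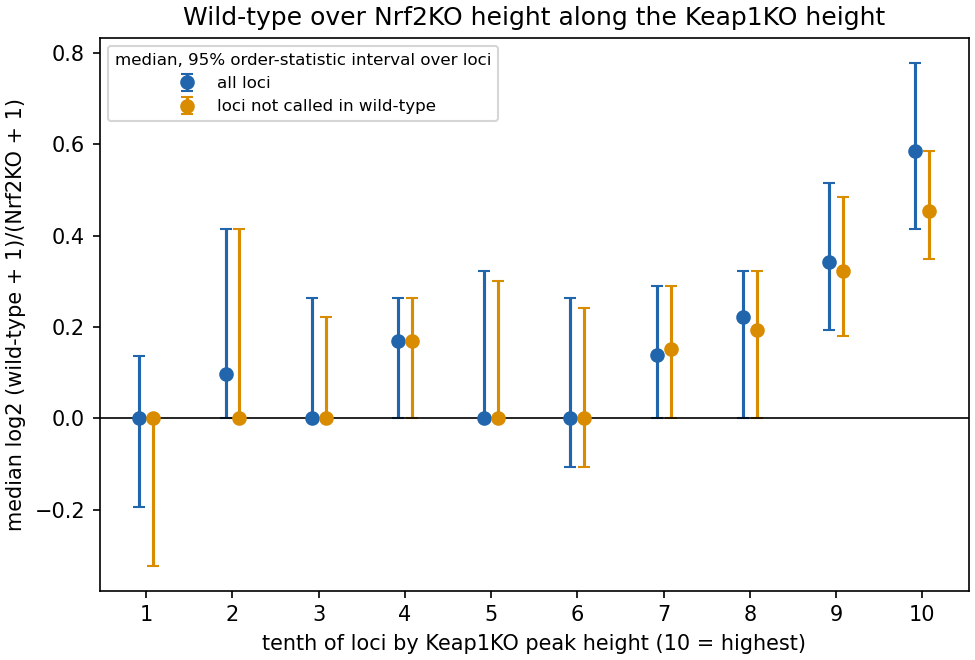
Median log2 ratio of wild-type to Nrf2KO (vertical) in 10 groups of loci ranked on Keap1KO height (horizontal, 10 the highest), for all loci and for loci not called in wild-type; bars are 95% order-statistic intervals over loci. The highest group lies at 0.58 for all loci and at 0.45 without those called in wild-type.

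Keap1KO stood above Nrf2KO at most loci. Txn1 had 194 against 7 (24.4-fold), Gsta4, a glutathione transferase, 67 against 2 (22.7-fold), and Adh7, an alcohol dehydrogenase, 48 against 1 (24.5-fold). With so low a height in Nrf2KO, the folds at Gsta4 and Adh7 depend more on the pseudocount than that at Txn1. Nrf2KO was listed at 0 at Zfp418, Tspan3, Tenm2, Tbcel, Tspan17, Cep192, Agpat9 and Sema4f, where Keap1KO heights ran from 23 to 28. The highest Nrf2KO heights were at Maff, which encodes a small Maf protein that pairs with Nrf2, with 17 (26 in Keap1KO), at Osbp (18 in Keap1KO), Angptl2 (15) and Whsc1l1 (14), with 15 each, and at the proteasome subunit gene Psmd1 with 14 (47 in Keap1KO). Psmd1 was not alone at this height, since a locus called in both wild-type and Keap1KO also had 14 in Nrf2KO.

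The median log2 ratio of Keap1KO to Nrf2KO was 1.91 (1.85 to 1.96), with 1245 loci at least 2-fold higher and 2 lower. Loci with a height at least 2-fold above Nrf2KO in wild-type or Keap1KO numbered 1246 (85.3%, 83.4 to 87.1), and 214 were not 2-fold above it. The same selection by calls applies.

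Among the lists, 55 of 121 Nrf2 pathway genes had a locus (45.5%, 36.4 to 54.8), against 7.67% of protein-coding genes. Keap1KO was at least 2-fold above wild-type at 51 of their 53 loci (1285 of all 1460) and above Nrf2KO at 52 (1245 of all). Wild-type was above Nrf2KO at 42 of the 53 (786 of all). Their median log2 ratios were 2.17 for Keap1KO over wild-type, 0.81 for wild-type over Nrf2KO and 3.04 for Keap1KO over Nrf2KO. Among matched random lists these stood at percentiles 99.6, 99.995 and 100. Of the 20 tallest Keap1KO loci, 13 were listed under a pathway gene, against 3.84% of all loci. Random lists were matched only within 10 bins of mean height, and such tall loci share the highest bin with lower ones. The highest of 10 groups by Keap1KO height ran from 34 to 194. These percentiles and those of the single lists can thus partly reflect height, and finer matching was not tried.

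Glutathione synthesis had 7 of 13 genes with a locus, all at least 2-fold above wild-type in Keap1KO, a rule met by 1285 of all 1460 loci. Among the 7 was Gclc, a subunit of the enzyme that starts glutathione synthesis (13.5 in wild-type, 4 in Nrf2KO, 56.5 in Keap1KO). The thioredoxin list had 5 of 11, with wild-type above Nrf2KO at all 5, and included Txnrd1, thioredoxin reductase (12, 5 and 77). Quinone and carbonyl reduction had 8 of 20, 7 of them at least 2-fold above wild-type in Keap1KO, with Aox1 at 11, 8 and 86, Cbr3 at 20, 9 and 81 and Aldh3a1 at 7, 7 and 49. Glutathione transferases had 12 of 22 at 10 loci, with 9 at least 2-fold above wild-type. The locus of Gstp1 (10.5, 4.5 and 89) is shared with its near-identical neighbour Gstp2, so its assignment is uncertain.

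The NADPH and pentose phosphate list had 5 of 10 genes, all at least 2-fold above wild-type in Keap1KO, with Taldo1, transaldolase, at 8, 2 and 44. Heme and iron had 3 of 10, among them Hmox1, heme oxygenase, at 11.5, 3 and 39.5 (outside the rule for named loci). Conjugation and export had 6 of 17, with the heme transporter gene Slc48a1 at 11, 10 and 46. Regulators of the pathway had 9 of 18, with Osgin1 at 11, 6 and 87 and Ppard, a nuclear receptor, at 14, 10 and 49. For Keap1KO over wild-type, the thioredoxin and the quinone lists lay above the 95th percentile (95.6 and 99.95). The thioredoxin list fell below it with a pseudocount of 0.5 (94.7), with the filter on mean height (92.8) and with all regions of a gene averaged (93.6). Glutathione synthesis rose above it with a pseudocount of 5 (97.5), and glutathione transferases with all regions averaged (95.1). For wild-type over Nrf2KO these were glutathione transferases (99.6), NADPH (96.9) and heme and iron (95.9, only 3 loci). NADPH fell below it with regions within 10 kb of the gene start (94.9) and with a pseudocount of 5 (93.0), and a minimum of 5 loci per list leaves out heme and iron. Thioredoxin rose above it with a pseudocount of 5 (95.3). For Keap1KO over Nrf2KO they were glutathione synthesis (97.8), thioredoxin (98.9), glutathione transferases (98.7) and NADPH (98.4). Of these, glutathione transferases fell to 93.2 with the filter on mean height and NADPH to 93.0 within 10 kb of the gene start, and conjugation and export rose to 95.7 with all regions averaged.

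**Figure D3:**
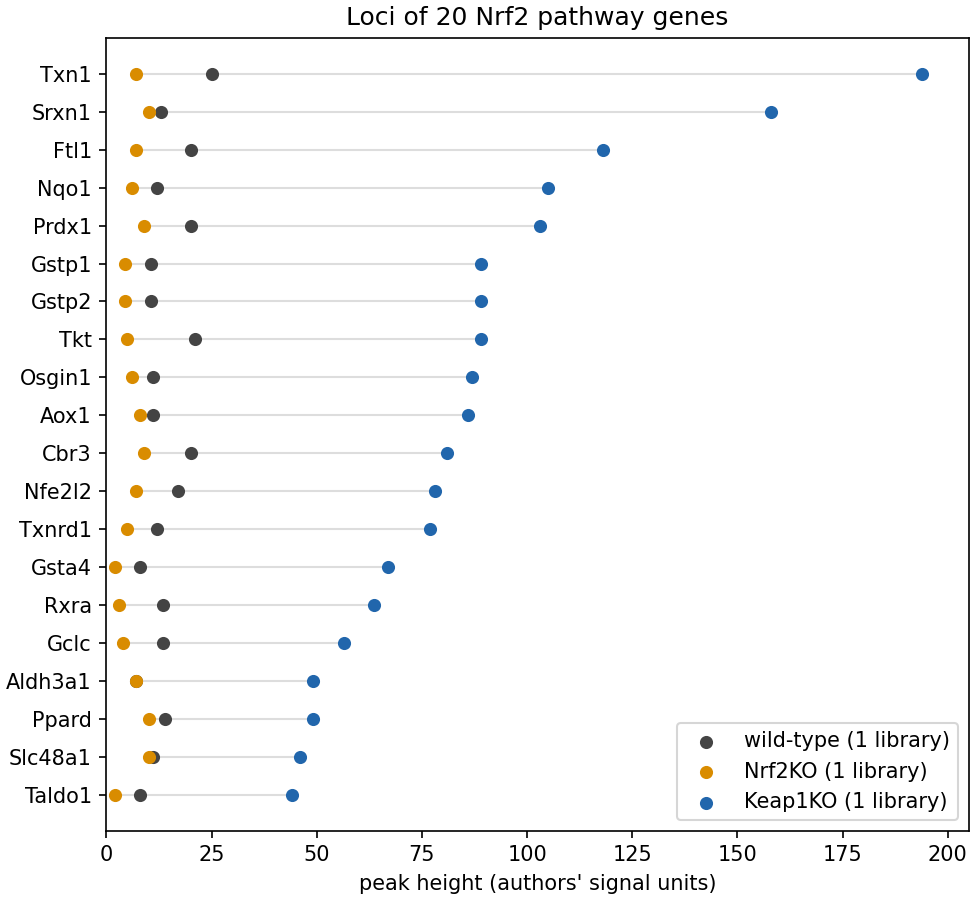
Peak heights in the 3 libraries at the 20 Nrf2 pathway list genes with the highest Keap1KO height, 1 point per library and locus. Keap1KO heights run from 44 at Taldo1 to 194 at Txn1. That Keap1KO is the highest of the 3 at each gene follows from this choice, since no locus exceeded 32 in wild-type or 17 in Nrf2KO.

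Of the lists outside the pathway, glycolysis had 9 of 40 genes with a locus, all 9 at least 2-fold above wild-type in Keap1KO, with the glucose transporter gene Slc2a1 at 12, 5 and 54. Genes of squamous differentiation had 0 of 35 (exact upper limit 10%), and basal squamous genes 4 of 20, with Notch1 at 9, 11 and 36 and Pax9 at 3, 6 and 16. AP-1 and immediate early genes had 5 of 17, with Fosl1 at 4, 2 and 27 and Ier3 at 7, 8 and 23. Muscle genes had 2 of 25 (Lmod1 and Ttn), fibroblast and endothelial genes 2 of 16 (Vim and Dpt), immune genes 1 of 16 (Cd68) and housekeeping genes 2 of 24 (Hprt and Tbp).

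The proteasome list had 17 of 31 genes with a locus (54.8%, 36.0 to 72.7). Its median height was 7 in wild-type, 7 in Nrf2KO and 21 in Keap1KO, against 8, 4.5 and 35 for the pathway lists. Keap1KO was at least 2-fold above Nrf2KO at 12 of the 17 and wild-type above Nrf2KO at 9. Vcp, an ATPase that unfolds ubiquitinated proteins, had 10 in wild-type, 5 in Nrf2KO and 44 in Keap1KO. The list's median ratios stood at percentiles 5.82 for Keap1KO over wild-type and 8.73 for Keap1KO over Nrf2KO. The random lists were not matched on distance to a gene start, and 88.2% of the list's loci lay within 1 kb of one. Over all loci there, the median log2 ratios were lower than farther away. They were 1.42 against 1.85 for Keap1KO over wild-type and 1.29 against 2.17 for Keap1KO over Nrf2KO. Its Psmb1 locus is also that of Tbp in the housekeeping list, with 10, 7 and 2.

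**Figure D4:**
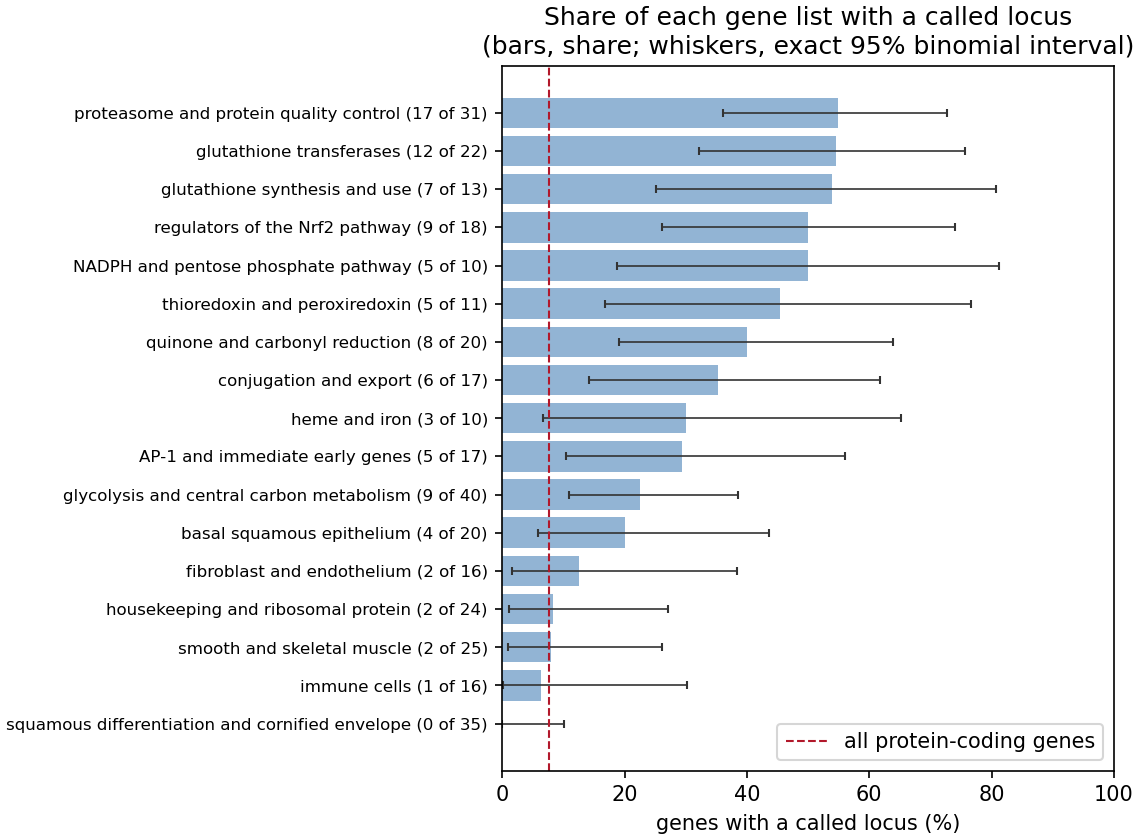
Share of each fixed gene list with a called locus (horizontal, percent), as bars with exact 95% binomial intervals over genes; the dashed line marks the 7.67% of protein-coding genes. The proteasome list reaches 54.8% and the squamous differentiation list 0%.

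Loci lay within 1 kb of the nearest gene start in 454 of 1460 cases (31.1%, 28.7 to 33.5). A locus of more than 1 region was placed by its interval closest to a start, while its height is the mean over its regions. Of the 1246 loci at least 2-fold above Nrf2KO, 24.1% (21.7 to 26.6) lay there, and of the other 214, 72.0% (65.4 to 77.9). The median Nrf2KO height was 7 within 1 kb of a start and 4 farther away, against 6.58 and 4.5 in wild-type and 17 and 18 in Keap1KO. The median log2 ratio of wild-type to Nrf2KO was 0.00 (−0.14 to 0.00) near starts and 0.32 (0.26 to 0.36) away from them. With loci ranked by Keap1KO height into 4 groups, the mean Nrf2KO height was higher near starts by 3.28, 3.26, 3.34 and 2.72.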

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

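The settings with 1 value per gene, loci more than 1 kb from a start, loci not called in wild-type, at least 5 loci per list and wild-type scaled to Nrf2KO were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library. Of the 721 values listed under an alternative, 4 changed sign. Many could not, since counts and shares have no sign and a pseudocount cannot reverse the ratio of a single locus. By a margin on size, 35 values of the main results moved and 65 did not. Of the other values, 101 moved and 516 did not. The 65 include the counts of calls on standard chromosomes, which were copied from the main values because that limit removed nothing. Where a value moved, the cause was not tested, except that filters leave fewer loci and a larger pseudocount shrinks ratios by construction. Unknown depth limits all ratios between libraries.

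With calls limited to heights of at least 18, the median of called regions, 903 Keap1KO and 11 wild-type regions were left, with 10 called in both, 893 in Keap1KO only and 1 in wild-type only. With any region of at least 12 counted as called, Keap1KO had 1592, of which 1480 in Keap1KO only, Nrf2KO had 49 and 71 were shared by wild-type and Keap1KO. A pseudocount of 0.5 gave median log2 ratios of 1.83 for Keap1KO over wild-type and 2.04 for Keap1KO over Nrf2KO, and 1 list above the 95th percentile for Keap1KO over wild-type. A pseudocount of 5 gave 1.25, 0.13 (wild-type over Nrf2KO) and 1.35, with 58 loci higher and 14 lower in wild-type than in Nrf2KO and 0 lower in Keap1KO than in Nrf2KO, and 3 lists above the 95th percentile for Keap1KO over wild-type, against 2.

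Loci of at least the median mean height left 661 higher and 0 lower for Keap1KO over wild-type, 120 and 38 for wild-type over Nrf2KO, 632 and 0 for Keap1KO over Nrf2KO, 632 loci 2-fold above Nrf2KO and 1 list above the 95th percentile for Keap1KO over wild-type. Loci more than 1 kb from a start gave medians of 1.85, 0.32 and 2.17, with 1 lower for Keap1KO over wild-type and 0 for Keap1KO over Nrf2KO. Loci not called in wild-type gave 0 lower in both Keap1KO comparisons. With 1 value per gene, Keap1KO over Nrf2KO had a median of 1.83 and 4 lower. Scaling wild-type gave a median of 0.14 over Nrf2KO. Within 5 kb of a start lay 46.4% of loci.

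The basal squamous list, at 0.08 for wild-type over Nrf2KO, went to −0.26 with the filter on mean height and to −0.26 with regions within 10 kb of the gene start. The AP-1 list, at −0.17, went to 0.28 with that filter and to 0.28 with all regions of a gene averaged. For wild-type over Nrf2KO, 2 lists lay above the 95th percentile with regions within 10 kb of the gene start and 2 with at least 5 loci per list, against 3. For Keap1KO over Nrf2KO, 5 lay there with all regions of a gene averaged, 3 with the filter and 3 within 10 kb, against 4. Neither the basal nor the AP-1 list has a direction in this comparison. Limiting the table to standard chromosomes removed nothing. Not run were the motif searches, an overlap over most of each interval (no interval lengths), an average over the region (the table has 1 height per library) and a scaling on regions called in all libraries (0 in Nrf2KO).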

Other observations

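Some tall loci lay outside the fixed lists and were chosen after their values were seen. Among the 20 tallest in Keap1KO were Sh2d6 (19 in wild-type, 7 in Nrf2KO and 136 in Keap1KO), Slc22a12 (7, 5 and 71), Reep3 (8, 5 and 68) and Snx29 (18, 6 and 68). Cat, which encodes the catalase that breaks down hydrogen peroxide, had 9, 3 and 71 at a locus 4737 bp into the gene. The locus shared by Neat1, Gm9783 and Frmd8 had 21.7, 9.67 and 82.3.

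The tests below were chosen after the result was seen, except the test of Keap1KO reads in the wild-type library. In all, 4 patterns were examined. The higher Nrf2KO height near gene starts was tested first and was then left out here in favour of the proteasome pattern once that list's share was known. Its values stand with the positions of the loci.

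Wild-type stood above Nrf2KO at the loci with the highest Keap1KO height. A difference in overall scale would move all loci alike, but the median log2 ratio in the highest of 10 groups exceeded that of the 5 lowest by 0.58 (0.42 to 0.78). Selection by the wild-type call is argued against by a difference of 0.45 (0.34 to 0.58) without the loci called there. Reads of the Keap1KO library in the wild-type library were not told apart from binding by the test made. The share of the Keap1KO excess seen in wild-type differed by −2.48 percentage points (−6.60 to 1.49) between loci near and far from gene starts. Such reads would give equal shares, but binding could give them too, so the test cannot decide. Binding of Nrf2 in the wild-type esophagus at the loci most occupied without Keap1 stays a hypothesis.

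Proteasome genes were listed with a locus in 17 of 31 cases, against 2 of 24 housekeeping genes. Background at active gene starts stays open, since 88.2% of the list's loci lay within 1 kb of a start, against 49.1% of pathway loci, and Nrf2KO heights were higher there. At the 15 proteasome loci near starts the median log2 ratio of Keap1KO to Nrf2KO was 1.64 (0.85 to 2.00). Background alone was predicted to give an interval that includes no difference between the libraries, and that was not seen. The prediction cannot decide, because nearly all loci near starts were chosen by a call in Keap1KO, which raises the ratio. The median exceeded that of 439 other loci near starts by 0.36 (−0.45 to 0.74). Binding of Nrf2 at these genes in wild-type was not decided either, with a median log2 ratio of wild-type to Nrf2KO of 0.19 (−0.32 to 0.85). The Psmb1 locus, shared with Tbp, counts in both lists.

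At the 12 loci called in wild-type only, calls at the level of the background may be the source. The median log2 ratio of Keap1KO to Nrf2KO there was −0.063 (−0.68 to 0.46), though these loci were by construction not called in Keap1KO. Binding in wild-type that is lost without Keap1 stays open, since wild-type over Nrf2KO differed from that of the loci called in both by −0.26 (−0.59 to 0.11). Wild-type was above Nrf2KO at all 12, with a median log2 ratio of 0.81 (0.50 to 1.12), although the call in wild-type selects its height upwards there. Of the 12, 9 lay within 1 kb of a gene start.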
